A study of Drosophila melanogaster with 3 samples.

How the data were processed

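The samples were 3 biological replicates, numbered as such in the labels, of embryos of both sexes aged 0 to 24 h from a transgenic Drosophila melanogaster line expressing CG8944 fused to GFP. Chromatin was sheared by sonication to a size range of 200 to 800 bp, per the labels, and recovered with an antibody against GFP. All replicates came from the same line and form 1 group, so that no comparison between conditions was possible. A control alignment entered the authors' peak calling, per the file listing deposited with the samples, but no control library was analysed here.

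The files used were peak lists in narrowPeak format on the dm6 build, with dm3 lists as an alternative. Per the deposited file listing, each replicate had a relaxed list of peaks and background, called by the authors against a control alignment. A further relaxed list came from the 3 replicates pooled, and the reproducible list was derived from all of these by an irreproducible discovery rate (IDR) threshold. The aligner, peak caller, versions and IDR threshold are not given in the sources used here. Each peak carries the authors' signal value, whose scale is not stated. It was therefore used only to rank or describe peaks within 1 list. The deposited −log10 q-value reached a common maximum in 60.4% of reproducible peaks and was not used for ranking. The summit is the authors' deposited offset within each peak. All 3511 reproducible peaks were found in the pooled list with the same start, end and summit, and they were the 3511 entries of that list with the highest signal. Peaks had a common width of 400 bp in 80.2% of reproducible peaks. The lists of replicates 1 and 2 held exactly 30000 entries each, which limits how far down weak sites can be compared. Replicate lists shared 0.767% to 1.32% of summit positions and no signal value, and were counted as separate samples. Read depth was unknown, since the lists hold no counts, and no interval that needs it was computed.

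Coordinates are 1-based on dm6. Genes, transcription start sites (TSSs) and features came from the Ensembl annotation BDGP6.54, release 115, whose arm lengths equal those of dm6. Transposable elements were left out, which left 18164 genes on arms 2L, 2R, 3L, 3R, 4 and X. A promoter was the 500 bp on either side of a TSS. Each summit took the first class that applied among promoter, 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic. The background was the 19963 pooled relaxed entries that overlapped no reproducible peak by 1 bp or more. For the spread between replicates, each share was recomputed in the 3511 strongest entries of each replicate. Gene lists (34) and consensus motifs (24) were fixed before the data were examined, and 15 gene names of those lists were brought up to date from synonyms afterwards; 1 listed name was not found. Occupancy tests used the genes with a relaxed summit within 500 bp of a TSS. Reproducible peaks are themselves relaxed entries, so this choice leaves out genes with no entry, which count as unoccupied among all annotated genes.

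Shares were compared with two-sided Fisher's exact tests, with 95% Woolf intervals for odds ratios and Wilson intervals for shares. Sides of the TSS were compared with an exact binomial test, and median signals with a permutation test of 100000 resamples. Families of tests over classes, lists, motifs and 6-mers were adjusted by the Benjamini-Hochberg method at 0.05. Motifs and 6-mers were sought on both strands within 50 bp of the summit; 6-mers were ranked on 2L and 2R and the 10 leading ones tested on 3L, 3R and X. GC-matched background was drawn a single time at random within bins of 5% GC, so calls close to the threshold could change with another draw. Peaks are not replicates, so these p-values do not carry the spread between embryo collections.

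The genes named were set by rule before the data were examined. They are the 20 reproducible peaks with the highest signal with the gene of the nearest TSS, 4 occupied members with the highest signal from each list past the threshold, at most 2 from each other list, and CG8944. Alternatives were the part of the peaks with the higher signal, the stronger background entries, random positions (10 per peak), TSS windows of 200 and 1000 bp, other gene universes, sequence windows of 25 and 100 bp, other overlap rules, dm3 lists, and leaving out each replicate in turn. In the last case, peaks had to overlap one of the strongest entries of both remaining replicates.

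The steps were tested on simulated data, with planted lists and shares near those called in the real data. With an occupancy of 65% planted in 78 ribosomal protein genes the list was called in 100% of 100 draws, and with 65% planted in 17 insulator genes in 45.0%. With 15% planted, tRNA genes were called in 95.0% and snoRNA genes in 82.0% of draws. Lists with nothing planted were called in 0.241% of tests. Genes were drawn independently there, whereas in the data neighbouring genes can share a peak, so this is no false-call rate for the data. A 6-mer planted in 10% of windows ranked first, and none was called without planting. Both sets of windows were drawn at random from the background. The simulation therefore does not cover the difference in GC content between peaks and background. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.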

Results

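Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map where a CG8944-eGFP fusion protein sat in the genome of Drosophila melanogaster embryos. The transgenic line carried CG8944 joined at its C terminus to green fluorescent protein, and chromatin was recovered with an antibody against GFP. Embryos of both sexes, 0 to 24 h old, gave 3 biological replicates of 1 group. The data were peak lists on the dm6 build. They held 30000, 30000 and 27393 entries for replicates 1, 2 and 3, 23886 for the pooled replicates, and 3511 reproducible peaks that had passed the authors' irreproducible discovery rate (IDR) threshold. Read depth was unknown because the lists hold no read counts. Intervals and p-values over peaks therefore cover the sampling of peaks, and the spread between replicates is given separately.

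The replicates were first compared for how far they reported the same sites. The same regions led in each of them. The strongest reproducible peak, 1400 bp upstream of cbt and inside an intron of ush, ranked 1, 2 and 2 in replicates 1, 2 and 3. The peak at the promoter of CG14100 ranked 2, 1 and 1, and the peak at Ugalt, which encodes a UDP-galactose transporter, ranked 4, 3 and 3. All 20 strongest peaks lay among the 100 strongest entries of every replicate, with 23 as the lowest rank. Of the 3511 reproducible peaks, 86.8% ± 0.221 (SD, n = 3) overlapped one of the 3511 strongest entries of a replicate by 1 bp or more. For 2457 peaks (69.98%) this held in all 3 replicates, and for 11 peaks in none. The strongest entries of replicate pairs overlapped by 77.9% ± 0.732 (SD over 3 pairs). Across peaks, which are not independent replicates, Spearman's rho of the caller's signal was 0.772 for replicates 1 and 2, 0.753 for 1 and 3, and 0.806 for 2 and 3. Since the reproducible peaks were selected from these replicates for agreement, the shares are not an independent estimate of reproducibility.

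The strongest sites lay mostly at promoters. Of the 20 peaks with the highest signal, 14 had a summit within 500 bp of an annotated transcription start site (TSS), 4 were in introns and 2 were intergenic. The peak at cbt (FBgn0043364, a zinc-finger transcription factor gene) covered 2L, 480880 to 481300, with a signal of 3177 in the pooled list. The 20 bp on either side of its summit read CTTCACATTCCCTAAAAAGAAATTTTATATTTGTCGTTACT. The peak at CG14100 (FBgn0036889) covered 3L, 19590414 to 19590814, with its summit 96 bp upstream of the TSS and a signal of 3165. Its summit sequence was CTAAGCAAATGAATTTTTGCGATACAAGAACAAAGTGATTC. At Ugalt (FBgn0024994; X, 2703698 to 2704083) the summit was 42 bp upstream and the signal 2520. At px (FBgn0003175, 2R, 22514110 to 22514499) it was 203 bp upstream of a TSS that lies within the gene, with a signal of 2406.

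Chro and ph-p, genes of chromatin proteins, were among these strongest sites. Chro (FBgn0044324), which encodes the chromodomain protein Chromator, had a peak at 3L, 22878694 to 22879104, with its summit 103 bp downstream of the TSS and a signal of 2139. The Polycomb group gene ph-p (FBgn0004861) had a peak at X, 2137178 to 2137567, 499 bp upstream of a TSS, with a signal of 2009. That distance lies at the edge of the promoter window. Adf1, a transcription factor gene, held the last of the 20 peaks, in an intron 808 bp downstream of a TSS (signal 1549). The kinase gene Lk6 had an intronic peak 965 bp upstream of its nearest TSS (signal 2095), and CG11050 an intronic peak 1021 bp downstream (signal 1869). The intergenic sites were 912 bp upstream of lncRNA:CR45643 and 11929 bp downstream of the start of CG13323. The promoters of Art3, CG1888, mRpL41, Shc, PNPase, Tcs5, lncRNA:CR44619, GstE13 and CenG1A carried the rest, with signals from 1586 at CenG1A to 1985 at Art3. At ph-p, CG1888 and PNPase the summit lay inside the gene, upstream of a TSS within it.

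Reproducible peaks lay at promoters more often than the weaker regions of the same pooled list. A summit within 500 bp of a TSS was found for 1907 of 3511 reproducible peaks (54.3%, 95% Wilson interval 52.7 to 56.0). It was found for 4759 of 19963 relaxed entries that overlapped no reproducible peak (23.8%). The odds ratio was 3.80 (95% interval 3.53 to 4.09; two-sided Fisher's exact test, p = 3.92e-272). Among the 3511 strongest entries of each replicate the share was 53.7% ± 1.67 (SD, n = 3), against 22.0% ± 2.47 among the other entries, so the difference exceeded the spread between replicates. Against random positions on the same chromosomes, of which 13.6% lay at promoters, the odds ratio was 7.54.

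Coding exons were nearly empty of reproducible peaks. They held 15 summits (0.427%) against 4287 relaxed entries (21.5%; adjusted p = 2.02e-304, Fisher's exact test with Benjamini-Hochberg adjustment over 7 classes). The 3' UTR class held 0.712% against 2.57% (adjusted exact p = 5e-14) and the 5' UTR class 0.456% against 1.17% (adjusted exact p = 5.09e-05). Against random positions the coding exon call stayed (odds ratio 0.0289, adjusted exact p = 9.01e-173). The 5' UTR call was lost there (odds ratio 0.607, adjusted exact p = 0.0686). No GC-matched background was run for the classes, although relaxed entries were richer in GC than the peaks. Intergenic summits made up 12.02% against 16.9% (adjusted exact p = 1.19e-13). Introns held 31.3% and 33.1% (adjusted exact p = 0.0393), and the intron call was lost against the stronger background entries (odds ratio 0.945, adjusted exact p = 0.209) and with a promoter window of 200 bp (odds ratio 1.07). Other exons did not differ past the threshold (0.797% and 0.912%, adjusted exact p = 0.561). In the replicates' strongest entries coding exons held 1.19% ± 0.480 and introns 31.0% ± 0.869 (SD, n = 3).

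**Figure D1:**
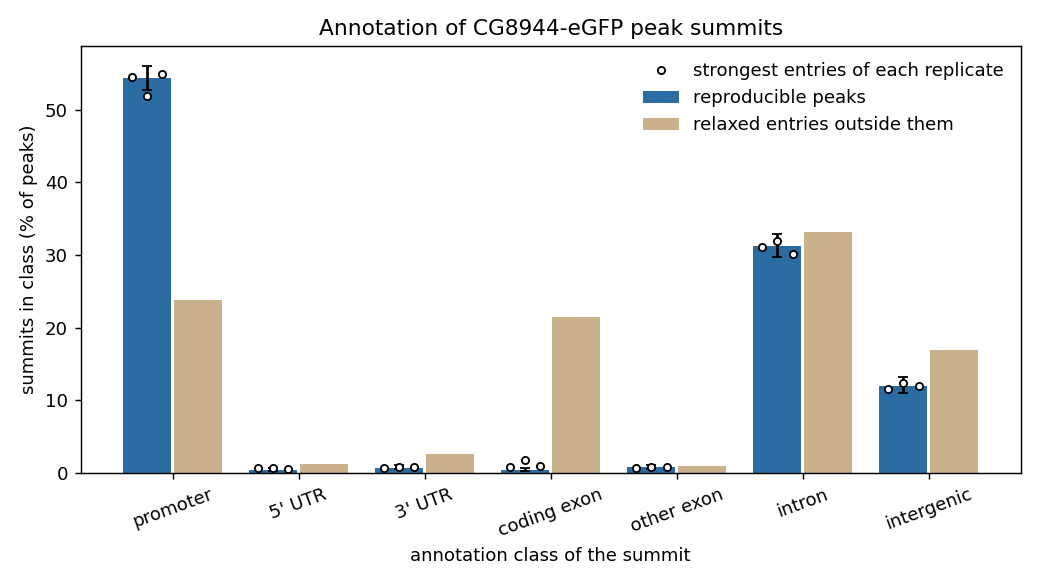
Share of peak summits (% of peaks, vertical axis) in 7 annotation classes for the reproducible peaks (blue, with 95% Wilson intervals) and the relaxed entries outside them (tan); open circles are the strongest entries of the 3 replicates. Promoters held 54.3% of reproducible and 23.8% of relaxed summits, and coding exons 0.427% and 21.5%.

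Promoter summits sat on the upstream side of the TSS. Of 1902 reproducible promoter peaks with a defined side, 1561 were upstream (82.1%, 95% Wilson interval 80.3 to 83.7; two-sided exact binomial test, p = 5.17e-186). The median position was -83 bp relative to the nearest TSS, with quartiles of -160 and -23. The strongest entries of the replicates were upstream in 79.8% ± 1.80 (SD, n = 3). Relaxed promoter entries were upstream in 49.2% (2336 of 4748).

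**Figure D2:**
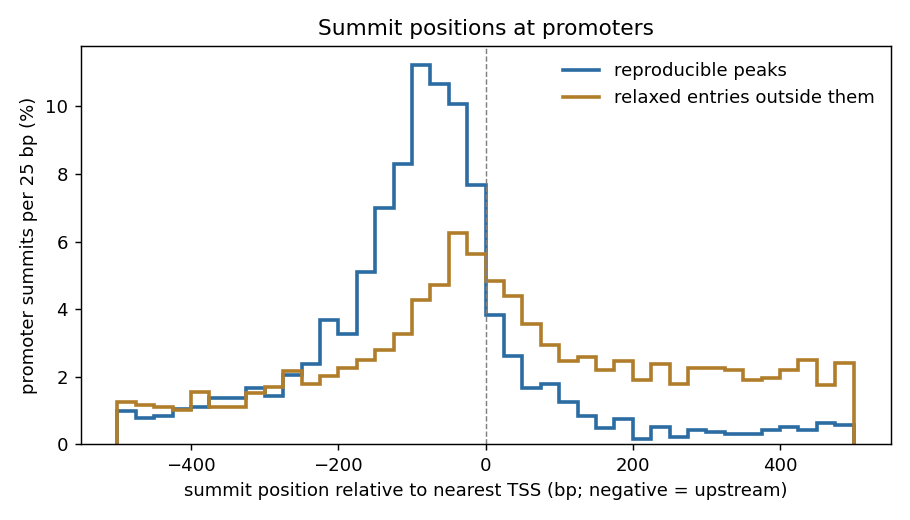
Position of promoter summits relative to the nearest TSS (horizontal axis, bp, negative upstream) as a share of promoter summits per 25 bp (vertical axis, %), for reproducible peaks (blue) and relaxed entries outside them (brown). Reproducible summits were upstream in 82.1% and relaxed entries in 49.2%.

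Promoter peaks were somewhat stronger than other peaks. Their median signal was 184 against 164 for the 1604 other reproducible peaks, a difference of 19.9 (two-sided permutation test with 100000 resamples, p = 1e-05, the smallest these resamples can give). Within the replicates' own lists the difference of medians was 3.49, 8.76 and 5.34 in replicates 1, 2 and 3, each on that list's own scale. Promoter peaks had the higher median in all 3 replicates. With a promoter window of 200 bp the difference was 9.34 (permutation p = 0.0306).

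Genes with closely spaced divergent promoters were counted as occupied more often than other genes, which the counting itself partly builds in. A gene counted as occupied when a reproducible summit lay within 500 bp of one of its TSSs. Of the 7256 genes with any relaxed summit that near, 2570 were occupied (35.4%). Occupancy was 45.7% (1727 of 3781) for genes whose TSS lay within 1000 bp of a head-to-head TSS of another gene, and 24.3% (843 of 3475) for the others (odds ratio 2.63, 95% interval 2.37 to 2.90; Fisher's exact test, p = 3.8e-82). Among all annotated genes the odds ratio was 4.82. One peak between such a gene pair counts for both genes. A gene can thus count as occupied through the promoter of its neighbour, which raises the share and both odds ratios for such genes. No comparison per promoter was run, so these values do not decide whether divergent promoters are themselves occupied more often. Genes are also not independent here, and the p-value is too small by an unknown amount.

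Among the 34 gene lists fixed beforehand, genes of cytoplasmic ribosomal proteins stood out. A reproducible promoter peak was present at 51 of 78 tested members (65.4%, 95% Wilson interval 54.3 to 74.99), against 35.1% of all other tested genes (odds ratio 3.49, 95% interval 2.19 to 5.58; Fisher's exact test, adjusted exact p = 2.35e-06 over 33 lists). In the replicates' strongest entries the share was 65.8% ± 4.12 (SD, n = 3), against 34.7% ± 1.10 of all tested genes. The members with the highest signal were RpS27 (FBgn0039300; 3R, 25245955 to 25247514; signal 825), RpL7 (FBgn0005593; 2L, 10201004 to 10202321; signal 756), RpL32 (FBgn0002626; 3R, 30045229 to 30046161; signal 671) and RpL23A (FBgn0026372; 3L, 1666288 to 1668654; signal 647). Each of these promoters held one of the strongest entries in 3 of 3 replicates.

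Genes of insulator and promoter-architecture proteins were also occupied more often, at 12 of 17 members (70.6%, odds ratio 4.39, adjusted exact p = 0.026, Fisher's exact test). Members with the highest signal were Chro (signal 2139), CG1792 (1026), Trl, which encodes GAGA factor (427), and Cp190, which encodes an insulator cofactor (335). The replicates' strongest entries gave 68.6% ± 6.79 (SD, n = 3). This call rested on few genes. It was lost without replicate 2 (adjusted exact p = 0.0764), without replicate 3 (adjusted exact p = 0.0737), with protein-coding genes only (adjusted exact p = 0.0981), with a 200 bp window (adjusted exact p = 0.175) and in the stronger-signal part of the peaks (adjusted exact p = 0.28).

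Genes of tRNAs, snoRNAs and cuticle proteins were occupied less often. The share was 16.9% for tRNA genes (14 of 83, odds ratio 0.367, adjusted exact p = 0.00238) and 13.0% for snoRNA genes (9 of 69, odds ratio 0.271, adjusted exact p = 0.000424; Fisher's exact tests). No promoter peak was found at any of 25 tested cuticle protein genes (adjusted exact p = 0.000394), and the Wilson interval reached 13.3%. In the replicates' strongest entries the shares were 14.9% ± 3.87, 15.9% ± 3.83 and 0% ± 0 for the same lists (SD, n = 3). Occupied tRNA genes with the highest signal were tRNA:Tyr-GTA-1-8 (580), tRNA:Gln-TTG-2-1 (320), tRNA:Phe-GAA-1-2 (282) and tRNA:Glu-TTC-1-5 (190). Occupied snoRNA genes were led by snoRNA:Psi28S-2949 (387), snoRNA:Psi18S-1275 (332), snoRNA:Or-CD11a (307) and snoRNA:Or-CD13 (300). The peak of snoRNA:Psi18S-1275 was also that of RpS29, and the peak of snoRNA:Or-CD11a that of RpL28, the ribosomal protein genes these snoRNA genes lie within. The peak of tRNA:Phe-GAA-1-2 was also that of RpL17. At snoRNA:Or-CD13, 1 of 3 replicates had one of its strongest entries. The snoRNA call was lost with a 1000 bp window (odds ratio 0.771, adjusted exact p = 0.67) and in the stronger-signal part of the peaks (adjusted exact p = 0.28). The cuticle call was lost in that part (adjusted exact p = 0.1) and with a 200 bp window (adjusted exact p = 0.0705). Many tRNA and snoRNA genes lie in clusters or inside host genes, so that their promoters are not independent.

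**Figure D3:**
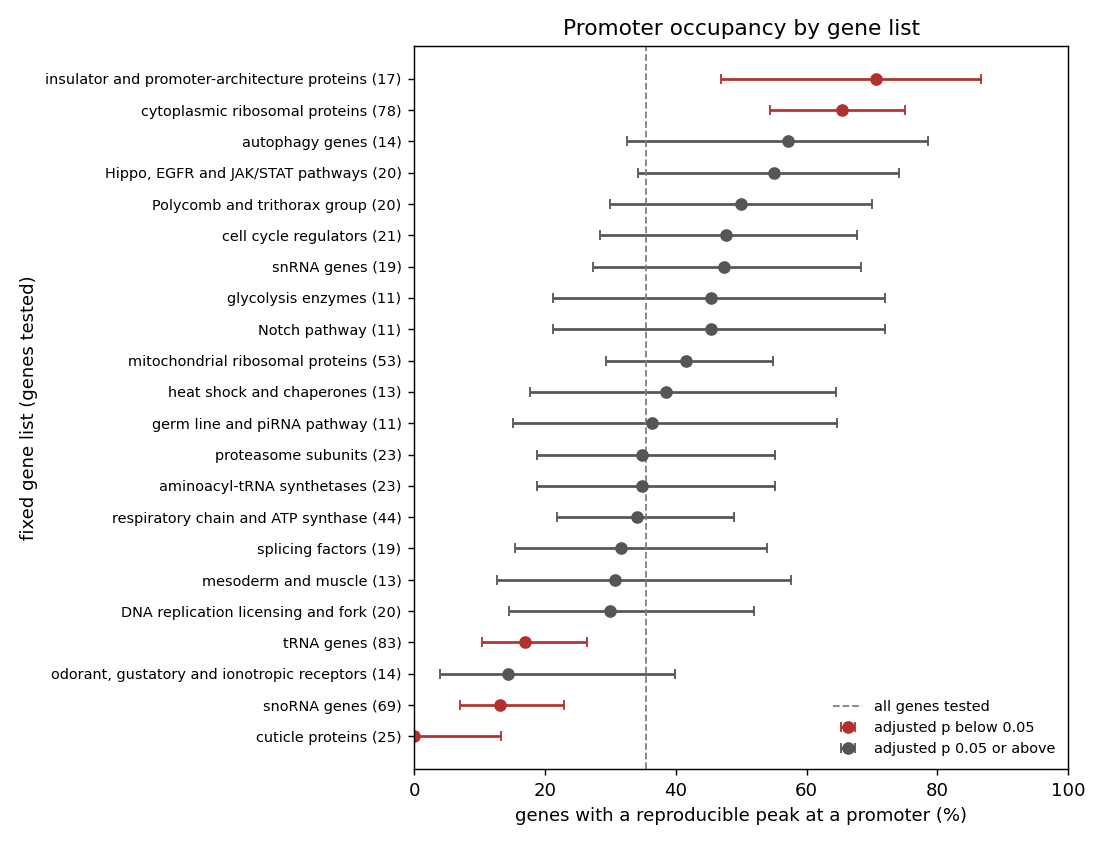
Share of tested genes with a reproducible peak at a promoter (%, horizontal axis) for each fixed list with at least 10 tested genes (vertical axis, number tested in parentheses), with 95% Wilson intervals; the dashed line marks all tested genes (35.4%). Red points have an adjusted p below 0.05, led upward by insulator and promoter-architecture proteins (70.6%) and cytoplasmic ribosomal proteins (65.4%).

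The other lists did not pass the threshold with the planned main settings. Of the growth and housekeeping lists, mitochondrial ribosomal proteins were occupied at 22 of 53 genes, led by mRpS10 (signal 1985, the peak it shares with Art3) and mRpL41 (1856). Respiratory chain and ATP synthase genes were occupied at 15 of 44 (ND-MWFE, 567), proteasome subunits at 8 of 23 (Rpn5, 348), aminoacyl-tRNA synthetases at 8 of 23 (SerRS, 456) and glycolysis enzymes at 5 of 11 (Gapdh2, 469). Occupancy was 9 of 19 for snRNA genes (snRNA:U1:95Ca, 242), 6 of 20 for DNA replication genes (dpa, 413), 10 of 21 for cell cycle regulators (Dp, 488) and 6 of 19 for splicing factors (SNRPG, 246). Heat shock and chaperone genes were occupied at 5 of 13 (Hsp27, 352), and autophagy genes at 8 of 14 (Atg17, 450). No replication-dependent histone gene had a relaxed summit near its TSS, so that list was not tested. Among all annotated genes, where a gene without a relaxed entry counts as unoccupied, 4 of these lists passed as higher: mitochondrial ribosomal proteins (adjusted exact p = 0.00221), glycolysis enzymes (0.0493), cell cycle regulators (0.00652) and autophagy genes (0.0126).

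Developmental gene lists were small among the tested genes. Polycomb and trithorax group genes were occupied at 10 of 20 (ph-p, 2009; brm, 280), and genes of the Hippo, EGFR and JAK/STAT pathways at 11 of 20 (spi, 504; hpo, 337). The latter list passed with a 1000 bp window (odds ratio 5.56, adjusted exact p = 0.00106, against 2.23 with 500 bp) and among all annotated genes (adjusted exact p = 0.00352). With the 500 bp window it did not pass (adjusted exact p = 0.409). With that window, its odds ratio without 1 of the replicates was 1.68, 1.37 or 1.39 (replicate 1, 2 or 3 left out) and did not pass either. Leaving out a replicate was not run with the 1000 bp window. Gap and maternal patterning genes were occupied at 3 of 5 (bcd, 412) and dosage compensation genes at 3 of 5 (Sxl, 210; msl-1, 153). No occupied member was found among 4 Hox genes, 8 dorsoventral patterning genes, 1 pair-rule gene and 3 chorion protein genes. Segment polarity genes were occupied at 1 of 7 (smo, 186), proneural and neuroblast genes at 2 of 7 (elav, 588), mesoderm and muscle genes at 4 of 13 (sls, 521) and endoderm and gut genes at 2 of 3 (fkh, 301). Haemocyte and immune genes were occupied at 1 of 6 (imd, 395), germ line and piRNA genes at 4 of 11 (stwl, 228), Notch pathway genes at 5 of 11 (aph-1, 416), ecdysone cascade genes at 2 of 8 (Eip75B, 391) and chemosensory receptor genes at 2 of 14 (Ir60e, 161). Among all annotated genes the Polycomb and trithorax group passed as higher (adjusted exact p = 0.0137) and the chemosensory receptors as lower (adjusted exact p = 7.34e-09). The few members tested limited what these tests could detect.

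Some promoter elements were more common in the reproducible peaks than in the relaxed entries, and others were not. In windows of 50 bp on either side of the summit, the DNA replication-related element (DRE, TATCGATA) occurred in 2.42% against 0.751% (odds ratio 3.28, adjusted exact p = 3.17e-15). The core site of the insulator protein BEAF-32, CGATA, occurred in 18.7% against 11.7% (odds ratio 1.74, adjusted exact p = 9.13e-27). Ohler motif 7 occurred in 4.07% against 1.74% (odds ratio 2.39, adjusted exact p = 3.17e-15). In the replicates' strongest entries the shares were 2.31% ± 0.377, 18.2% ± 0.399 and 3.89% ± 0.172 (SD, n = 3). Of the 24 motifs fixed beforehand, 12 were more frequent and 3 less frequent past an adjusted p of 0.05 (Fisher's exact test, Benjamini-Hochberg adjustment). The less frequent ones were the downstream promoter element (DPE, 93.9% against 95.6%, odds ratio 0.715, adjusted exact p = 8.28e-05), the E-box CAGCTG (4.44% against 6.11%) and CA repeats (1.14% against 1.95%). The DPE consensus used here, RGWYV, matched most windows of both sets, so its matches do not locate such elements. GAGA, Zelda, PHO, initiator (odds ratio 0.939) and CTCF core matches did not differ past the threshold in this comparison. Zelda matches were lower past it with a 100 bp window (odds ratio 0.526, adjusted exact p = 0.00254) and between promoter entries (0.345, adjusted exact p = 0.0453), as were initiator matches between promoter entries (0.759, adjusted exact p = 0.0126). The core of Ohler motif 1, GGTCACA, was higher past it with a 100 bp window (1.67, adjusted exact p = 1.28e-06). The calls of the full Ohler motif 1 and of Ohler motif 6 were lost in the stronger-signal peaks, against the stronger background and with a 25 bp window.

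Fewer motifs differed once base composition was matched. The windows held 37.0% GC in reproducible peaks and 47.4% in relaxed entries. Against relaxed entries matched in GC content, 7 motifs passed the threshold, 3 of them in the direction opposite to the unmatched comparison. DRE (odds ratio 2.15, adjusted exact p = 0.000364), CGATA (1.63, adjusted exact p = 4.91e-12) and Ohler motif 7 (2.88, adjusted exact p = 1.76e-10) were still more frequent. The E-box CAGCTG turned higher (1.41, adjusted exact p = 0.025), and the poly-A run (0.741, adjusted exact p = 0.00733) and the homeodomain motif (0.751, adjusted exact p = 0.00639) turned lower. The calls of DPE (0.985, adjusted exact p = 0.96) and CA repeats (0.738, adjusted exact p = 0.386) were lost, so none of the 3 motifs called less frequent above was called so here. Between promoter entries without GC matching, 9 motifs were higher past the threshold. Among them were DRE (1.58, adjusted exact p = 0.00498), CGATA (1.46, adjusted exact p = 1.66e-07) and Ohler motif 7 (1.97, adjusted exact p = 3.15e-07). The Su(Hw) core had the largest odds ratio of these 9 (3.31, adjusted exact p = 0.000557). Promoter entries were then matched in GC content as well, a comparison chosen after seeing the data. The DRE (1.26, adjusted exact p = 0.347), CGATA (1.24, adjusted exact p = 0.059) and Su(Hw) core (1.86, adjusted exact p = 0.274) calls were lost there. That of Ohler motif 7 was not (1.99, adjusted exact p = 0.000156). Between all entries matched in GC content, the TATA box, higher in the unmatched comparison (16.1% against 8.18%), had an odds ratio of 0.893 (adjusted exact p = 0.221). The GATA motif had 0.965 there (adjusted exact p = 0.809). For the Su(Hw) core, higher in the unmatched comparison (2.05, adjusted exact p = 0.000255), it was 1.05 (adjusted exact p = 0.96). The CTCF core, which did not differ past the threshold against the unmatched background, was more frequent than in the matched one (odds ratio 1.90, adjusted exact p = 1.57e-06). It also passed in GC-matched promoter entries (1.69, adjusted exact p = 0.0157).

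The leading 6-mers were A/T-rich. Ranked on arms 2L and 2R, the 10 most enriched contained only A and T, and all 10 were more frequent in reproducible peaks on the held-out arms 3L, 3R and X. TTAAAA led, in 27.6% of 2188 windows against 11.5% of 12244 (odds ratio 2.91, adjusted exact p = 2.64e-74, Fisher's exact test). With GC-matched background a different set of 10 was found, none shared with the first, and 4 of them passed on the held-out arms. These were TATCGA (odds ratio 1.84, adjusted exact p = 3.43e-06), part of the DRE, ACAGTG (1.57, adjusted exact p = 0.000235), GCGCCA (1.48, adjusted exact p = 0.0141) and CGTGAC (1.81, adjusted exact p = 0.0487). The matched background was a single random draw, so the call of CGTGAC, close to the threshold, could change with another.

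The X chromosome held a larger share of reproducible peaks than of relaxed entries. It carried 676 of 3496 reproducible peaks on the 5 large arms (19.3%) and 2786 of 19854 relaxed entries (14.0%; odds ratio 1.47, 95% interval 1.34 to 1.61; Fisher's exact test, p = 3.01e-15). The replicates' strongest entries gave 18.9% ± 0.728 (SD, n = 3). Per Mb, reproducible peaks numbered 28.7 on X and 28.5 on 2L, with 24.8 to 25.4 on the other large arms. Relaxed entries numbered 118 per Mb on X and 148 to 165 per Mb on those autosomal arms.

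The tagged gene itself carried no reproducible peak at its promoter. CG8944 (FBgn0030680) lies on the minus strand of X, 15741343 to 15746231. Within 1000 bp of it, 1 reproducible peak was found, at X, 15740196 to 15740595 (signal 265, rank 868). Its summit lay 947 bp beyond the 3' end of CG8944, in a 3' UTR, and the nearest TSS was that of CG8206, 1166 bp away. An entry at that position ranked 902, 998 and 704 in replicates 1, 2 and 3. Near the CG8944 TSS the pooled list held a relaxed entry with its summit 47 bp away (signal 79.1, rank 5346) that was not among the reproducible peaks.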

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

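The pooled dm3 list held 62 entries on unplaced and heterochromatin sequences, which entered no comparison, since the dm3 comparison of the X share used the large arms alone. They are listed for lying outside the compared sequences, and with no control list analysed here the count is no evidence of binding there. The highest signal among them was 103, below the lowest signal of a reproducible dm3 peak (112), and 0 reproducible dm3 peaks lay there. Outlying samples were not sought, since the group has 3 samples.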

How the results depend on the processing

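Promoter share, X share, signal difference, summit side and divergent promoter occupancy kept their direction and their side of the threshold under every alternative run for them, and 5 or 6 of the 7 classes passed the threshold in each. For divergent promoter occupancy, every alternative still counted a shared peak for both genes. The odds ratio of promoter summits ranged from 2.91 (stronger background) to 7.54 (random positions). With a replicate left out it was 4.04 to 4.13, though this setting only filters the same peaks. A GC-matched background for promoter share, and one for motifs in promoter entries only, were chosen after the data were seen. Overlap of reproducible peaks with the replicates moved by more than the main setting's replicate SD (0.221), to 83.7% with summits within 100 bp, 76.8% with reciprocal overlap of 50%, 89.3% with the list and its comparison both limited to their stronger part, and 87.2% with dm3 lists, whose own SD (0.456) exceeds that move. Gene lists past the threshold numbered 5, against 2 with the stronger-signal peaks, 3 with a 200 bp window, 2 with protein-coding genes only (the tRNA and snoRNA lists were not testable there, and the insulator call was lost) and 13 with all annotated genes, where genes without any relaxed entry count as unoccupied, which fixed the outcome for the histone list. Motifs past the threshold fell from 15 to 7 with GC-matched background and to 2 with GC-matched promoter entries, and called 6-mers from 10 to 4 with GC-matched background. Both matched settings also compare fewer background entries. Among motifs called in the main setting, odds ratios that crossed 1 with GC-matched background were 0.893 for the TATA box, 1.41 for the E-box CAGCTG, 0.965 for GATA, 0.989 for the TCT initiator, 0.741 for the poly-A run and 0.751 for the homeodomain motif. In promoter entries only, those of Ohler motif 1 (0.762) and STAT (0.913) did. In GC-matched promoter entries the called ones that reached or crossed 1 were 0.675 for Ohler motif 1, 0.856 for Ohler motif 6, 0.931 for the TATA box, 1.04 for DPE, 1.43 for the E-box CAGCTG, 1 for GATA, 0.966 for the TCT initiator, 0.939 for the poly-A run, 0.790 for the homeodomain motif and 0.700 for STAT. The intron class moved to 1.07 with a 200 bp window. Beyond GC matching, the cause of these changes was not tested. Read depth is unknown and its effect could not be examined.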

Other observations

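Of the tests of this part, the motif comparisons with GC-matched background and in promoter entries were planned before the data were examined. The choice of DRE, CGATA and Ohler motif 7, and how many of them would have to be called, came afterwards. The promoter test with GC-matched background and the count of motifs in GC-matched promoter entries were added later, before their values were seen. The tests by signal bin, of upstream summits against relaxed entries, of the leading 6-mers with GC-matched background, of motif 7 alone and of the X share against length were chosen after the results were seen. Promoter share varied with signal among the reproducible peaks. It was 60.9% in the strongest of 4 signal bins (534 of 877, 95% Wilson interval 57.6 to 64.1) and 49.3% in the weakest (433 of 878, 46.0 to 52.6; odds ratio 1.60, Fisher's exact test, p = 1.23e-06). Upstream summits were more common among reproducible than among relaxed promoter entries (82.1% against 49.2%, odds ratio 4.73, Fisher's exact test, p = 1.85e-143).

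Protein-coding genes made up most of the occupied genes, with 2381 of 13945 annotated genes carrying a reproducible promoter peak (17.1%), against 152 of 3261 ncRNA genes (4.66%) and 9 of 32 snRNA genes (28.1%). Chromosome 4 held 15 reproducible peaks, or 11.1 per Mb, with 10.6 ± 2.38 per Mb (SD, n = 3) in the replicates' strongest entries, against 24.8 to 28.7 per Mb on the large arms. Relaxed entries were sparse there as well, with 80.9 per Mb against 118 to 165 per Mb. Annotated transposable elements held 7 reproducible summits (0.199%), against 0.401% of relaxed entries and 5.82% of random positions; how reads from repeats were treated is not given in the sources used here.

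The excess of promoters among the reproducible peaks was weighed against the GC content of the background, since relaxed entries were richer in GC. With background entries matched in GC content the odds ratio was 3.48, against 3.80 unmatched, which argues against GC content as the whole cause. General chromatin accessibility stays open as a possible explanation, because no control immunoprecipitation was analysed here. No biological explanation was tested, since the design has 1 group.

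The A/T-rich 6-mers may follow from the difference in GC content between peaks and background. Mean GC was 37.0% in the peaks, 42.2% at random positions and 47.4% in relaxed entries, so the peaks were also low in GC. Matching GC in the same windows removes much of any excess of A/T-only 6-mers. It therefore cannot tell whether the peaks or the background are the source. On the held-out arms, 1 of the 10 leading 6-mers (TTAAAA, odds ratio 1.22) was still higher past the threshold with GC-matched background, and another (AAATAA, 0.830) was lower past it. DRE, CGATA and Ohler motif 7 behaved otherwise, as 3 of these 3 motifs were higher with that background (odds ratios 2.15, 1.63 and 2.88). They are the only motifs called higher in the main setting that stayed so there, so the count of 3 is no support in itself. Every DRE match also holds CGATA, so these 2 motifs are not separate. For each motif, its own odds ratio argues against GC content alone as the whole cause. In promoter entries without GC matching, 3 of the 3 were again higher. The odds ratios were 1.58 for DRE (95% interval 1.19 to 2.11), 1.46 for CGATA (1.28 to 1.65) and 1.97 for motif 7. These values argue against a larger share of summits within 500 bp of a TSS as the whole cause. The 3 motifs were chosen after the results were seen, so this count is no support in itself either. In promoter entries matched for GC content as well, 1 of the 3 passed: Ohler motif 7, with an odds ratio of 1.99, while DRE (1.26, 0.902 to 1.76) and CGATA (1.24, 1.06 to 1.44, adjusted exact p = 0.059) did not. The DRE and CGATA calls ended with lower odds ratios and with fewer background entries, 1884 in place of 4759. Motif 7 was not alone in passing there, as the CTCF core did too (1.69, adjusted exact p = 0.0157). Promoter share and GC content together are argued against as the whole cause for motif 7, and stay open for DRE and CGATA. The test of motif 7 alone was chosen after its value was seen, so it is no independent support. Summit position within promoters was not matched, with medians of -83 bp in reproducible and 4 bp in relaxed promoter entries. Position therefore stays open for all 3 motifs.

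The X chromosome excess may reflect fewer background entries on X. The X share of reproducible peaks was 19.3% (95% Wilson interval 18.1 to 20.7), and X makes up 17.8% of the length of the large arms. The exact binomial p of the peaks against that length share was 0.0159. The share in the strongest entries was 19.5% (18.2 to 20.8) in replicate 2 and 19.2% (17.9 to 20.5) in replicate 3, both above the length share. In replicate 1 it was 18.1% (16.9 to 19.4), an interval that includes it. As the replicates differ in this, the tables do not decide whether fewer background entries are the whole cause. Male and female embryos were pooled, which leaves X copy number open as well.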
